A study of Homo sapiens with 6 samples.

How the data were processed

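RNA was measured by paired-end sequencing in MDA-MB-231 cells, an established human breast cancer line, in 3 control libraries and 3 libraries of cells in which VASP was knocked down. Per the labels' protocols, cells were harvested 48 hours after transfection, RNA was taken up in Trizol, and libraries were made from 1 ug of total RNA with an Illumina TruSeq kit. Titles name an empty short hairpin vector (plko) and shVASP, whereas the characteristics and the treatment protocol name a negative control siRNA and a VASP siRNA delivered by transient transfection. Both sets of labels give the same grouping, and which reagent was used is left open.

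The values are whole-number counts of fragments per gene symbol, not normalized, which the authors deposited in a single table. Per the file headers, they were made with featureCounts 1.6.4 in paired-end mode over the exons of GENCODE release 32, including patches and alternate sequences, on GRCh38. Trim Galore 0.6.4 and STAR 2.7.1a are named in the submitters' processing notes, along with build hg38; their settings are not given in the sources used here. The header shows no strand option and no option for multi-mapping or multi-overlapping reads, so at the defaults of featureCounts strand was ignored and fragments with several alignments or touching the exons of several symbols were not counted. Genes with near-identical copies are therefore undercounted, a gene whose exons overlap another loses the shared fragments, and unspliced RNA of an antisense partner that covers an exon is counted with the gene. Per the file headers, a further column holds the merged exon length of each symbol in bases. All 6 count columns were checked to hold whole numbers of 0 or more.

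The 3 control columns are headed with names that extend the title of a single control sample by a further number, so each is known to be a control library but not which control sample it is. Control libraries are numbered here in the order of the table, as names only. The control names could also mean repeats of a single culture. Nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Pairs of libraries within a group differed by a chi-square per degree of freedom of 5.67 to 9.73 over genes, and pairs between groups by 21.9 to 28.7, so no pair agreed within sampling noise and each library was counted as 1 replicate.

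The table holds 61155 symbols, of which 26345 had a count of 0 in every library. Library totals ran from 28856610 to 30055503 counts, so 1 count is worth less than the floor of 3 counts, which lies at 0.0998 to 0.104 CPM across libraries. Genes were filtered with filterByExpr, which left 16633, scaled by TMM and tested with the two-sided quasi-likelihood test of edgeR 4.0.16 (glmQLFit, robust, and glmQLFTest) in R 4.3.3 with group as the sole term. P-values were adjusted by Benjamini and Hochberg's method over all genes tested, with a threshold of 0.05, and a second count took genes with an absolute log2 fold change of 1 or more. Fold changes are knockdown against control, the SE of a log2 fold change is its size divided by the square root of the test's F, and CPM are TMM-scaled and given as mean ± SD over n = 3. The biological coefficient of variation was 4.81%. Floors, and the intervals of count ratios, cover counting error only, while the other intervals cover spread across genes, which are not independent replicates.

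Before the data were examined, 41 gene lists were fixed, covering Ena/VASP partners, actin and adhesion, extracellular matrix, transcription factor targets, cell cycle, interferon and inflammation, stress, metabolism, RNA quality and markers of other cell types. Of these, 38 had at least 5 tested members, and the result of 1 of them is not reported here. They were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the 38 lists. Camera asks whether a list moved more than other genes. Camera with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in a single direction without comparing them with other genes, stand beside it. Of 1120 list symbols, 23 were matched through their Ensembl gene and 2 through a synonym. The genes named were set by a rule of the same date. It takes VASP, ENAH and EVL, the 12 largest increases and 12 largest decreases among protein-coding genes with an adjusted p under 0.05, a mean log2 CPM of 1 or more and groups that do not overlap, and up to 4 members of each list with the smallest p among those past the threshold.

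Gene type, GC content and 3' UTR sequence came from GENCODE release 29 on GRCh38 by Ensembl gene, with 56443 symbols matched, and coordinates came from the deposited table. A correction for GC content and length was added after the data were examined: per library, a natural spline with 5 degrees of freedom of each gene's deviation from its mean log2 CPM on GC content and on log exon length gave an offset for the same edgeR test, over the 16344 tested genes with a GC value. A search over 7-base words in 3' UTRs related 15789 words to the fold change in 10977 coding genes by a rank sum z, with VASP left out and after removing trends with the length and GC content of the 3' UTR and the GC content of the transcript. Its null was the highest absolute z over all words in 1000 permutations. It used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

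The gene test, the GC and length correction, camera at the preset correlation and the word search were tested on simulated data for the comparison of knockdown with control, with counts drawn from the real means and library sizes. Over 16383 genes, with changes seeded in genes of a mean log2 CPM above 1, 70% of those seeded with a 1.2-fold change were called, 92% at 1.5-fold and 100% at 2-fold and at 4-fold, and 0.0371% of unchanged genes were called. With a planted GC trend, 23.6% of unchanged genes were called before the correction and 0.0507% after it, while 85% of seeded changes were recovered. Camera called a list moved on purpose (adjusted p = 3.3e-122) and also 1 unmoved list with no shared member, and neither fry nor the estimated correlation was simulated. Simulated genes were drawn independently of each other, so camera was not tested on lists whose genes vary together between libraries. A word planted in the 3' UTR search over 10977 genes ranked 1. The alternatives were DESeq2's size factors and upper-quartile scaling, no filter except on genes at 0 throughout, a filter of 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, and leaving out each library in turn. Added after the data were examined were the GC and length correction, a count over genes with a GC value only, a test against a fold change of 1.2, and the lists without VASP or without genes that carry the 6-base word GTCGTC.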

Results

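VASP is an actin regulator of the Ena/VASP family that promotes filament elongation at the leading edge and at focal adhesions. To see how its loss alters gene expression, RNA was sequenced from MDA-MB-231, an established human breast cancer line with invasive, mesenchymal features, in 3 control and 3 VASP knockdown libraries harvested 48 hours after transfection. The libraries held 28856610 to 30055503 counts each, and 26986 to 27646 symbols had a count. The first principal component of log2 CPM held 51.6% of the variance and separated the groups, and the second held 14.8%.

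The knockdown lowered VASP mRNA in every library. VASP (ENSG00000125753, GRCh38 chromosome 19, 45506579 to 45526983, plus strand, 3538 bases of merged exons) had 4544, 5036 and 4708 counts in the control libraries and 396, 379 and 360 in the knockdown libraries. Its level went from 164 ± 9.04 CPM (SD, n = 3) to 12.7 ± 0.355 CPM (SD, n = 3), 12.9-fold lower (log2 fold change -3.69, SE 0.06, edgeR adjusted p = 8.3e-24). The other family members, ENAH (Mena) and EVL, did not pass the test. ENAH stood at 102 ± 3.74 CPM in control and 105 ± 2.08 CPM in knockdown (n = 3 each, log2 fold change 0.03, SE 0.05, adjusted p = 0.62). EVL, whose exons overlap DEGS2, stood at 18.1 ± 1.57 and 18.1 ± 0.541 CPM (n = 3 each, log2 fold change 0.00, SE 0.07, adjusted p = 0.98).

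**Figure D1:**
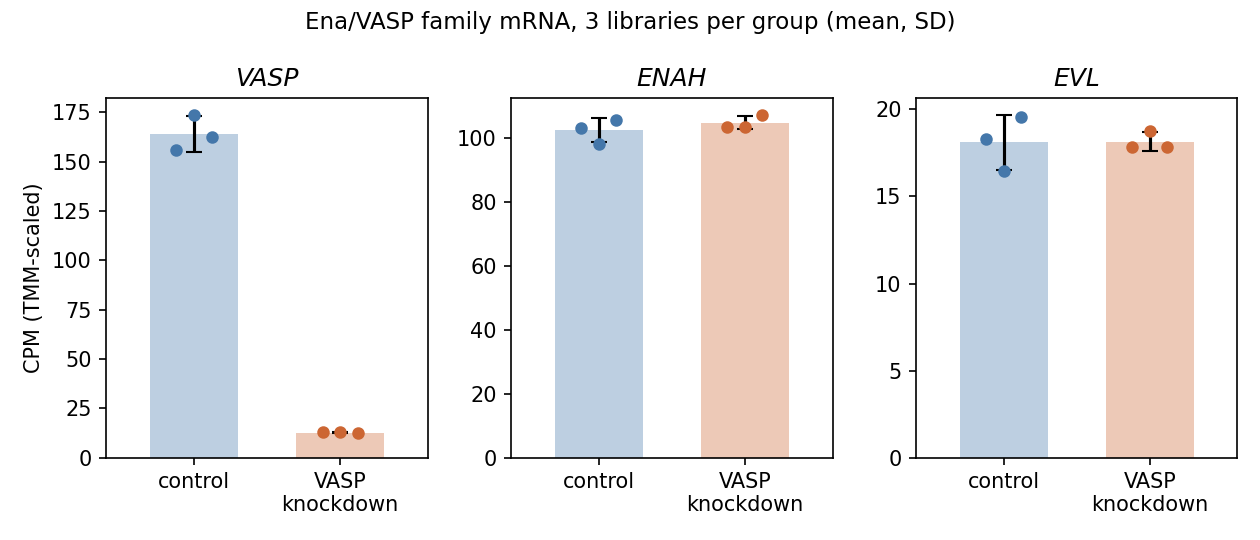
CPM (vertical axis, TMM-scaled, a separate scale for each gene) of VASP, ENAH and EVL, with a point for each library, bars at the mean and error bars of 1 SD over 3 libraries per group. VASP stood at 12.7 CPM in knockdown against 164 CPM in control, while the points of the groups overlap for ENAH and EVL.

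The response was broad and mostly small. Of 16633 genes tested, 3148 rose and 3039 fell, together 37.2%, with a median change of 1.23-fold. At an absolute log2 fold change of 1 or more, 69 genes rose and 150 fell, 219 together, against 363 without a low-count filter, 101 with a filter of 1 CPM in 3 libraries and 119 with DESeq2. Groups did not overlap in 47.6% of tested genes, where chance gives 10%. Fold change also followed GC content. In the decile of genes lowest in GC, at 39.7% or less, the median log2 fold change was 0.22, and in the highest decile, at 61.3% or more, it was -0.23 (Spearman correlation -0.54 across 12236 genes, which are not independent replicates). After a correction for GC content and length, 4503 genes passed, 2372 up and 2131 down, and 3473 of the 6145 calls that have a GC value passed in both fits, 3470 of them in the same direction. Against a fold change of 1.2 as the null, 953 genes passed, 324 up and 629 down.

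**Figure D2:**
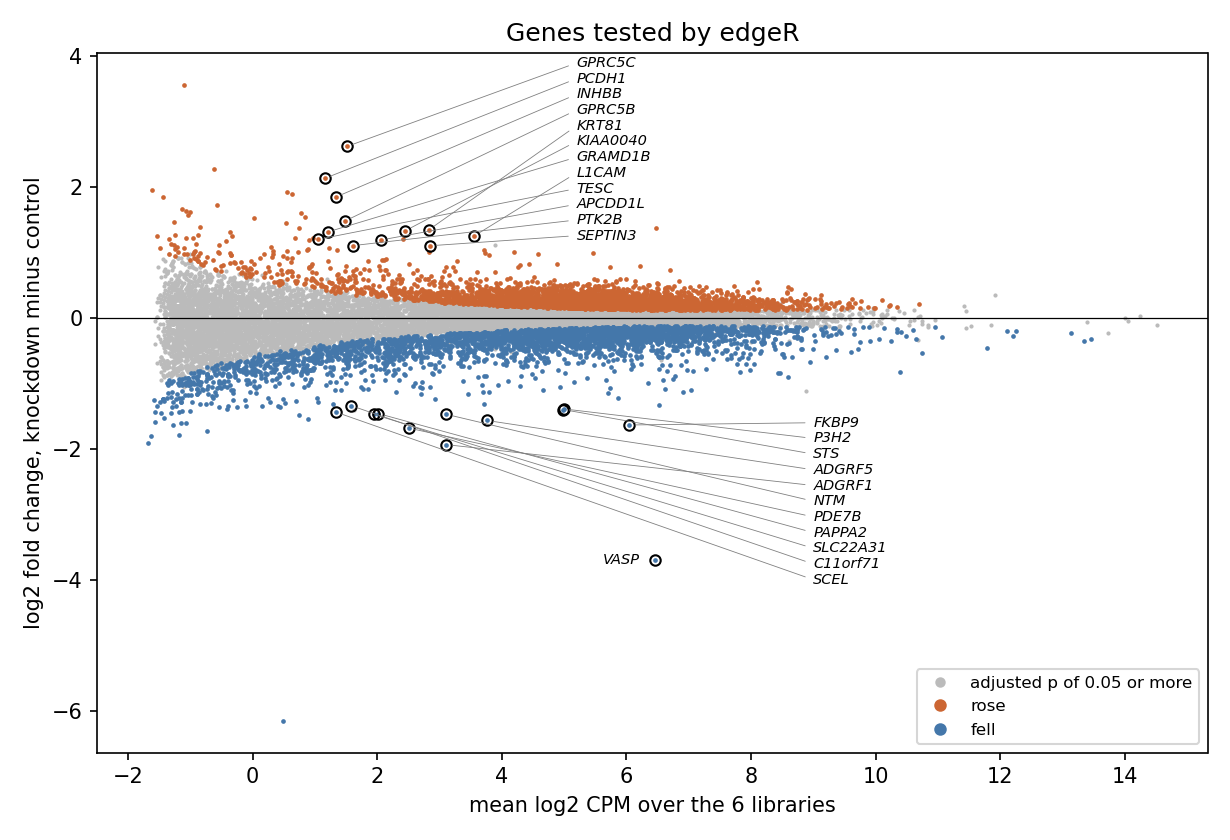
Log2 fold change (vertical axis, knockdown minus control) against mean log2 CPM over the 6 libraries (horizontal axis) for the 16633 genes tested, where colours mark the 3148 genes that rose and the 3039 that fell, and circles mark the named genes with the largest changes. VASP lies at -3.69, and most coloured points lie within 1 log2 unit of 0.

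**Figure D3:**
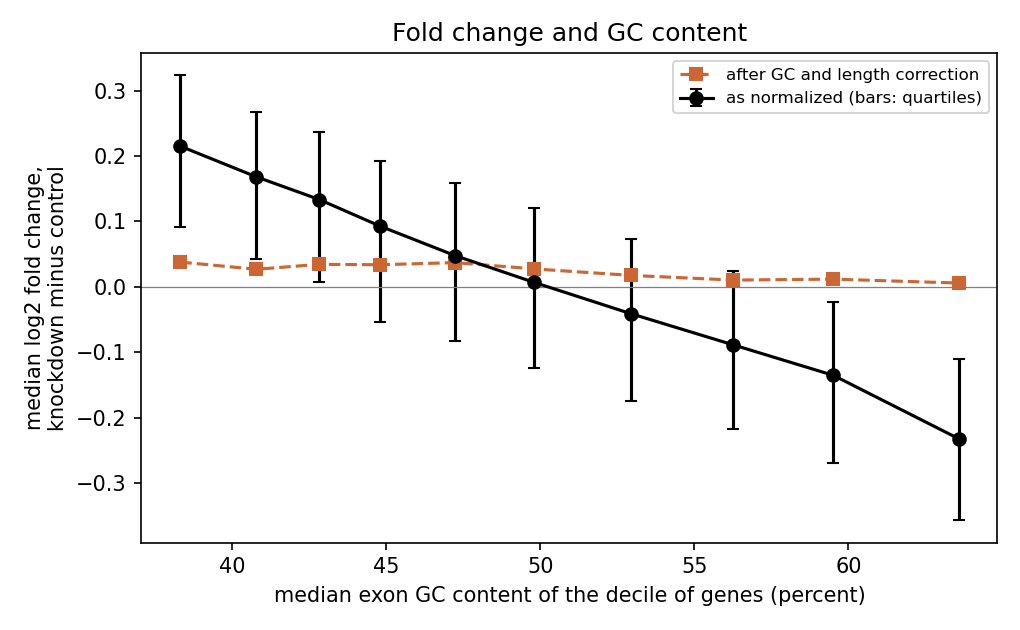
Median log2 fold change (vertical axis, knockdown minus control) of each decile of 12236 genes against its median exon GC content in percent (horizontal axis), with bars from the lower to the upper quartile, and the medians after correction as squares. The medians go from 0.22 to -0.23 before correction and from 0.04 to 0.01 after it.

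The 12 largest increases were of 2.15-fold or more. GPRC5C, an orphan G protein-coupled receptor, rose 6.16-fold (log2 fold change 2.62, SE 0.17, adjusted p = 4.4e-11), from 0.769 ± 0.0745 to 4.76 ± 0.572 CPM, and its relative GPRC5B, which shares exon sequence with IQCK, rose 2.79-fold. PCDH1, a protocadherin, rose 4.39-fold (log2 fold change 2.13, SE 0.20, adjusted p = 3.0e-08), and L1CAM, a cell adhesion molecule of the nervous system, rose 2.38-fold to 16.4 ± 1.11 CPM. INHBB, the beta B subunit of activin B and inhibin B, rose to 3.81 ± 0.471 CPM (log2 fold change 1.85, SE 0.18, adjusted p = 4.6e-08). The remaining increases among the 12 largest were KRT81, a hair keratin (2.55-fold), KIAA0040 (2.53-fold), the sterol transfer protein GRAMD1B (2.49-fold), TESC (2.30-fold), APCDD1L (2.29-fold), the FAK-related kinase PTK2B (2.15-fold) and SEPTIN3 (2.15-fold). All 12 were weakly expressed in control, from 0.769 CPM for GPRC5C to 6.87 CPM for L1CAM, which limits the precision of their folds.

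After VASP, the largest decrease was that of ADGRF1, an adhesion G protein-coupled receptor. ADGRF1 fell from 13.7 ± 1.49 to 3.57 ± 0.334 CPM, 3.82-fold (log2 fold change -1.94, SE 0.11, adjusted p = 2.1e-12), and its relative ADGRF5 fell 2.96-fold. The cAMP phosphodiesterase PDE7B, whose exons overlap an antisense gene that also fell, was 3.21-fold lower. FKBP9, a peptidyl-prolyl isomerase of the endoplasmic reticulum, fell from 99.7 ± 1.17 to 32.1 ± 0.772 CPM, 3.11-fold (log2 fold change -1.63, SE 0.05, adjusted p = 2.5e-17). P3H2, a collagen prolyl 3-hydroxylase, fell 2.62-fold from 46.0 ± 3.20 CPM, and the steroid sulfatase STS fell 2.64-fold from 46.1 ± 4.11 CPM. SLC22A31 (2.77-fold), the cell surface protein NTM (2.77-fold), the metalloproteinase PAPPA2 (2.75-fold), the cornified envelope precursor SCEL (2.71-fold) and C11orf71 (2.53-fold) completed the 12. The exons of SCEL, STS and C11orf71 overlap SCEL-AS1, PUDP and RBM7, so shared fragments were not counted. FKBP9, STS and C11orf71 carry the 6-base word GTCGTC in the 3' UTR, and of 611 genes with that word there 44.5% fell, against 30.0% of 1632 genes with it only elsewhere in the transcript and 18.6% of 8734 genes without it. These shares come from calls not corrected for GC content. With trends in GC content and 3' UTR length removed, the median log2 fold changes were -0.075, -0.015 and 0.033 in the same order.

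**Figure D4:**
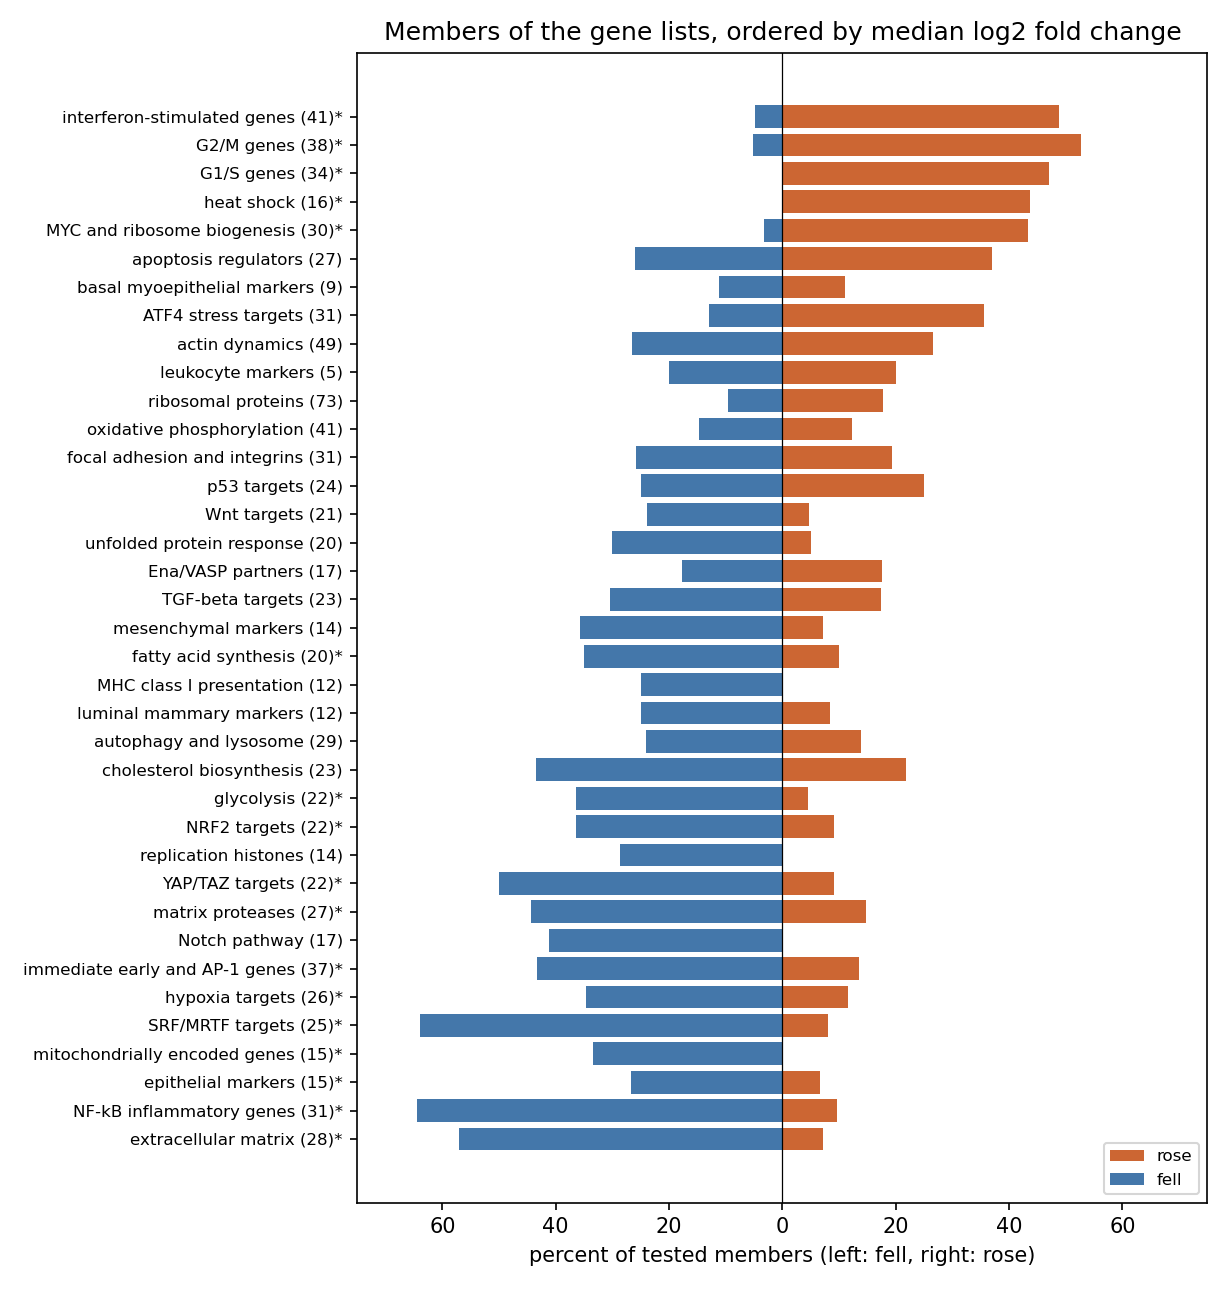
Percent of tested members (horizontal axis) that rose, to the right, or fell, to the left, in each gene list reported (vertical axis, with the number of tested members), ordered by median log2 fold change. Asterisks mark the 17 lists with a camera adjusted p under 0.05 at the preset correlation, such as extracellular matrix, where 16 of 28 fell, and G2/M genes, where 20 of 38 rose.

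Of the 38 lists, 17 passed camera, 5 up and 12 down, and all 17 lost the call with an estimated correlation, with 4 residual degrees of freedom behind that estimate. At the preset correlation, a grouping of the libraries that mixes control and knockdown gave as many as 20 lists. A camera p at that correlation therefore does not by itself tie a list to the knockdown. By fry, 18 lists passed, 12 of them among the 17, and 15 lists passed by fry when VASP itself was left out. Fry was run only on values not corrected for GC content. It does not compare a list with other genes, so the trend with GC content can enter its p-values throughout. Extracellular matrix genes fell together: of 28 tested, 16 fell and 2 rose (17 and 2 adjusted over the list alone), with a median log2 fold change of -0.31 (camera adjusted p = 4.4e-06, adjusted p = 0.58 with an estimated correlation, fry adjusted p = 0.027). TNC, the matrix glycoprotein tenascin C, fell 1.84-fold from 142 ± 4.04 CPM (adjusted p = 1.5e-12). AGRN, a heparan sulfate proteoglycan that carries the 3' UTR word, fell 1.79-fold, the collagen crosslinking enzyme LOX 1.42-fold, and the type IV collagen chain COL4A2 1.40-fold. After the GC and length correction 14 members fell and 5 rose, and the log2 fold change of AGRN went from -0.84 to -0.52. Matrix proteases and their inhibitors had 12 of 27 members down and 4 up, the same adjusted over the list alone (camera adjusted p = 0.036, 0.123 without control library 1, adjusted p = 0.58 with an estimated correlation, fry adjusted p = 0.046). In this list 7 members fell and 2 rose after the GC and length correction (camera adjusted p = 0.042). MMP14, the membrane-anchored collagenase, fell 1.36-fold, the tissue plasminogen activator PLAT 1.27-fold and ADAMTS1 1.52-fold, whereas the protease inhibitor SERPINE2 rose 1.23-fold.

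Targets of the actin-sensitive transcription factors SRF and MRTF fell: 16 of 25 fell and 2 rose, the same adjusted over the list alone, with a median log2 fold change of -0.20 (camera adjusted p = 6.5e-06, adjusted p = 0.19 with an estimated correlation, fry adjusted p = 0.00034). The filament crosslinker FLNA went from 2028 ± 39.7 to 1404 ± 71.2 CPM (1.44-fold lower, adjusted p = 9.6e-08). MYL9, a light chain of nonmuscle and smooth muscle myosin, and MYH9, a heavy chain of nonmuscle myosin, fell 1.31-fold and 1.28-fold, and MICAL2 fell 1.24-fold. MYH9 carries the 3' UTR word. After the GC and length correction 9 members fell and 1 rose, and the log2 fold changes went from -0.53 to -0.31 for FLNA, from -0.36 to -0.21 for MYH9 and from -0.39 to -0.23 for MYL9. YAP and TAZ targets had 11 of 22 down and 2 up (11 and 3 adjusted over the list alone), among them TGFB2 (1.29-fold), RBMS3 (1.31-fold) and F3, a carrier of the word (log2 fold change -0.26). Camera gave an adjusted p of 0.016, 0.0616 without knockdown library 2 and 0.070 after the GC and length correction (adjusted p = 0.58 with an estimated correlation, fry adjusted p = 0.028). With that correction 6 of the YAP and TAZ targets fell and 2 rose.

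The actin machinery itself moved in both directions. Of 49 actin dynamics genes 13 rose and 13 fell (18 and 14 adjusted over the list alone), with FLNA, LIMK1, MYH9 and MYL9 among those that fell (camera adjusted p = 0.67). LIMK1, which phosphorylates cofilin, fell 1.32-fold, with a log2 fold change that went from -0.40 to -0.24 after the GC and length correction. Of 31 focal adhesion and integrin genes 6 rose and 8 fell (8 and 9 adjusted over the list alone, camera adjusted p = 0.96), with a median of -0.004 and a mean of 0.002. With the GC and length correction 10 of these rose and 7 fell (median 0.053, camera adjusted p = 0.46). TNS1, a tensin that links integrins to actin, rose 2.05-fold from 8.48 ± 0.382 CPM (adjusted p = 6.3e-10), ITGA6 rose 1.35-fold, FERMT2 rose 1.28-fold (log2 fold change 0.35, 0.20 after the GC and length correction) and ITGB5 fell 1.41-fold. Of 17 Ena/VASP family members and partners, 3 rose and 3 fell, VASP included, the same adjusted over the list alone (camera adjusted p = 0.24, fry adjusted p = 0.0053). The fry call rests on VASP, without which the 16 others had a mean log2 fold change of -0.03 and adjusted p of 0.68 by camera and 0.25 by fry. LPP, a zyxin relative with the word, fell 1.22-fold and FBLIM1 fell 1.26-fold (log2 fold change -0.33, -0.16 after the GC and length correction).

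Genes that mark the mesenchymal state did not move as a group by camera, with 5 of 14 down and 1 up (adjusted p = 0.12, fry adjusted p = 0.028). FN1, fibronectin, fell 1.77-fold from 1726 ± 268 to 973 ± 53 CPM, ACTA2 fell 1.56-fold, and the repressor ZEB1 rose 1.38-fold. Epithelial markers had 4 of 15 down and 1 up, with a camera adjusted p of 0.044 (adjusted p = 0.58 with an estimated correlation, 0.23 after the GC and length correction, 0.0575 without control library 1, 0.0829 without control library 2 and 0.0536 without knockdown library 1, fry adjusted p = 0.028). MUC1 fell 1.85-fold, CLDN4 1.37-fold, and KRT7 1.24-fold from 495 ± 23.4 CPM (log2 fold change -0.30, -0.17 after the GC and length correction). TGF-beta targets had 7 of 23 down and 4 up (8 and 5 adjusted over the list alone, camera adjusted p = 0.25), with TGFBI 1.40-fold and LTBP3 1.42-fold lower, and the log2 fold change of LTBP3 went from -0.50 to -0.22 after the GC and length correction. The balance of these targets turned with that correction, to 4 down and 5 up (median log2 fold change 0.015, camera adjusted p = 0.95). In the mesenchymal and epithelial lists the counts adjusted over the list alone were the same.

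Inflammatory targets of NF-kB fell. Of 31 tested, 20 fell and 3 rose (21 and 3 adjusted over the list alone), with a median log2 fold change of -0.27 (camera adjusted p = 4.4e-06, adjusted p = 0.46 with an estimated correlation, fry adjusted p = 0.011). The neutrophil chemokine CXCL8 went from 229 ± 10.6 to 164 ± 6.37 CPM (1.40-fold lower, adjusted p = 8.8e-08), the cytokine LIF fell 1.41-fold, the leukocyte ligand ICAM1 fell 1.36-fold, and TNFAIP2, which carries the 3' UTR word, fell 1.42-fold (log2 fold change -0.51, -0.34 after the GC and length correction). Immediate early and AP-1 genes had 16 of 37 down and 5 up (17 and 5 adjusted over the list alone), with a camera adjusted p of 0.0069 (0.084 after the GC and length correction, adjusted p = 0.58 with an estimated correlation, fry adjusted p = 0.028). JUN fell 1.41-fold and the phosphatase DUSP1 1.39-fold, while KLF10 rose 1.32-fold and the antiproliferative gene BTG2 1.88-fold.

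Interferon-stimulated genes moved the other way. Of 41 tested, 20 rose and 2 fell, the same adjusted over the list alone, with a median log2 fold change of 0.20 (camera adjusted p = 3.7e-05, adjusted p = 0.58 with an estimated correlation, fry adjusted p = 0.025). The RNA-binding antiviral proteins IFIT2 and IFIT3 rose 1.74-fold and 1.66-fold, IFIT3 from 78.3 ± 1.12 to 130 ± 3.81 CPM (adjusted p = 3.1e-11). IFI44 rose 1.77-fold, and DDX58, the RNA sensor RIG-I, rose 1.52-fold. The tested genes of MHC class I presentation did not rise with them: of 12 tested, out of 20 listed, 3 fell and none rose by edgeR, the same adjusted over the list alone (camera adjusted p = 0.14), among them the chaperone CALR (1.29-fold). TAPBP, which carries the 3' UTR word, also fell, from 6.68 CPM. It lies on 4 further sequences of the annotation, and fragments with several alignments were not counted, so such genes are undercounted. Whether this also kept listed members out of the test was not examined, so the contrast with interferon-stimulated genes holds for the tested members only.

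Most of the cell cycle genes that changed rose, while the replication histones that changed fell. Of 34 G1/S genes 16 rose and none fell by edgeR, the same adjusted over the list alone (median log2 fold change 0.14, camera adjusted p = 7.3e-05, adjusted p = 0.63 with an estimated correlation, fry adjusted p = 0.12). The cyclins CCNE2 and CCNE1 rose 1.62-fold and 1.36-fold, CLSPN 1.37-fold and RFC3 1.28-fold. Of 38 G2/M genes 20 rose and 2 fell (22 and 2 adjusted over the list alone, median 0.16, camera adjusted p = 6.5e-06, adjusted p = 0.59 with an estimated correlation, fry adjusted p = 0.044). After the GC and length correction 16 G2/M genes rose and 3 fell (median 0.09, camera adjusted p = 0.0013). With it 19 G1/S genes rose and none fell (median 0.17, camera adjusted p = 2.6e-06). CCNA2, cyclin A2, went from 109 ± 4.77 to 151 ± 1.53 CPM (1.39-fold, adjusted p = 7.2e-08), and CENPF and the spindle checkpoint kinase TTK rose 1.40-fold and 1.43-fold. UBE2C, which carries the 3' UTR word, fell 1.39-fold. Replication histones had 4 of 14 down and none up by edgeR, the same adjusted over the list alone (camera adjusted p = 0.086, 0.0425 without control library 3), with HIST2H2BE 1.56-fold lower. MYC targets and ribosome biogenesis factors had 13 of 30 up and 1 down, the same adjusted over the list alone, with NOLC1 (1.28-fold) and DDX21 (1.32-fold) among them (camera adjusted p = 0.0026, adjusted p = 0.63 with an estimated correlation, fry adjusted p = 0.11). Heat shock genes had 7 of 16 up and none down by edgeR (8 and 1 adjusted over the list alone), led by HSPH1 (1.34-fold) and HSPA4L (1.27-fold, camera adjusted p = 0.014, adjusted p = 0.58 with an estimated correlation, fry adjusted p = 0.028). Several increases were smaller after the correction for GC content and length: log2 fold changes went from 0.47 to 0.34 for CCNA2, from 0.49 to 0.36 for CENPF, from 0.52 to 0.34 for TTK, from 0.35 to 0.20 for RFC3, from 0.42 to 0.27 for HSPH1, from 0.35 to 0.20 for HSPA4L and from 0.40 to 0.26 for DDX21.

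Among p53 targets 6 of 24 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.98, where camera and fry point up while the median and mean are -0.008 and -0.005), with BTG2 and CCNG1 (1.30-fold) up and GDF15 (1.34-fold) and TP53INP1 (1.44-fold) down. Apoptosis regulators had 10 of 27 up and 7 down (11 and 7 adjusted over the list alone, camera adjusted p = 0.24, fry adjusted p = 0.0088). PMAIP1, the BH3-only protein NOXA, rose 1.40-fold, CYCS rose 1.32-fold and the inhibitor BIRC3 1.40-fold. After the GC and length correction the log2 fold changes went from 0.38 to 0.20 for CCNG1 and from 0.48 to 0.30 for BIRC3. Ribosomal proteins had 13 of 73 up and 7 down (12 and 6 adjusted over the list alone, camera adjusted p = 0.30, 0.0171 without knockdown library 3), and RPS7 fell 1.51-fold from 279 ± 1.53 CPM.

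In metabolism, fatty acid synthesis genes had 7 of 20 down and 2 up (8 and 2 adjusted over the list alone), with a camera adjusted p of 0.044 (0.123 without control library 1, 0.0655 without knockdown library 3, adjusted p = 0.59 with an estimated correlation) and a fry adjusted p of 0.048 (0.051 when VASP was left out of the genes tested). FASN, fatty acid synthase, fell 1.46-fold from 435 ± 24.9 CPM, and SREBF1, a transcription factor of lipid synthesis, fell 1.41-fold. FADS2 and ELOVL5 fell 1.31-fold and 1.26-fold. After the GC and length correction the log2 fold changes went from -0.54 to -0.26 for FASN, from -0.49 to -0.25 for SREBF1 and from -0.40 to -0.26 for FADS2. Cholesterol synthesis genes had 10 of 23 down and 5 up, the same adjusted over the list alone (camera adjusted p = 0.18), with DHCR7 1.41-fold lower. Glycolysis genes had 8 of 22 down and 1 up, the same adjusted over the list alone, and ENO1 fell 1.22-fold from 2355 ± 143 CPM. Its camera adjusted p was 0.010 (adjusted p = 0.63 with an estimated correlation, fry adjusted p = 0.10), and after the GC and length correction, with 2 members down and an adjusted p of 0.29, the call was lost. Hypoxia targets had 9 of 26 down and 3 up (10 and 3 adjusted over the list alone, camera adjusted p = 0.011, 0.121 without control library 1, adjusted p = 0.66 with an estimated correlation, fry adjusted p = 0.15), among them the peptide hormone ADM (1.39-fold), ERO1A (1.23-fold) and LOX. Targets of the antioxidant regulator NRF2 had 8 of 22 down and 2 up, the same adjusted over the list alone, with AKR1B1 (1.46-fold), TXNRD1 (1.26-fold) and ABCC3 (1.51-fold) down (camera adjusted p = 0.014, adjusted p = 0.58 with an estimated correlation, fry adjusted p = 0.034).

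Mitochondrially encoded genes had 5 of 15 down and none up by edgeR, the same adjusted over the list alone, with a median log2 fold change of -0.23. MT-ND5 fell 1.37-fold and MT-ND4 1.25-fold. The camera adjusted p was 0.024, 0.128 without control library 1 and 0.195 without knockdown library 1 (adjusted p = 0.66 with an estimated correlation, fry adjusted p = 0.26). Their share of all counts, which also varies with RNA handling, was 13.7% to 15.1% in control libraries and 12% to 14.6% in knockdown libraries. Nuclear genes of oxidative phosphorylation had 5 of 41 up and 6 down (3 and 4 adjusted over the list alone, camera adjusted p = 0.83). The unfolded protein response had 6 of 20 down and 1 up, the same adjusted over the list alone, with PDIA4 1.30-fold and EDEM1 1.28-fold lower (camera adjusted p = 0.24, 0.042 after the GC and length correction, fry adjusted p = 0.044). ATF4 targets had 11 of 31 up and 4 down (12 and 7 adjusted over the list alone), with CHAC1 1.37-fold higher and the transfer RNA synthetase genes SARS and GARS 1.21-fold and 1.23-fold higher (camera adjusted p = 0.24, 0.011 after the GC and length correction). Autophagy and lysosome genes had 4 of 29 up and 7 down, the same adjusted over the list alone (camera adjusted p = 0.22), with the kinase ULK1 1.43-fold lower (log2 fold change -0.51, -0.26 after the GC and length correction).

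Notch pathway genes had 7 of 17 down and none up by edgeR, the same adjusted over the list alone (camera adjusted p = 0.081, 0.0463 without knockdown library 1, 0.49 after the GC and length correction, fry adjusted p = 0.028). The receptor NOTCH3 fell 2.06-fold from 26.4 ± 4.99 to 12.8 ± 1.51 CPM (adjusted p = 0.0010), and DTX4 fell 1.48-fold. Wnt targets and components had 5 of 21 down and 1 up, the same adjusted over the list alone (camera adjusted p = 0.67), with the coreceptor LRP5 1.47-fold lower (log2 fold change -0.56, -0.35 after the GC and length correction). Among markers of cell identity, luminal mammary genes had 3 of 12 down and 1 up (camera adjusted p = 0.39) and basal genes 1 of 9 up, EGFR (1.18-fold), and 1 down, MYLK (1.23-fold, camera adjusted p = 0.83). Of 5 tested leukocyte markers LAPTM5 rose 1.41-fold and LCP1, the actin bundler L-plastin, fell 1.63-fold from 271 ± 14.7 CPM (camera adjusted p = 0.56, fry adjusted p = 0.049, 0.052 when VASP was left out of the genes tested, with a median of 0.04 and a mean of -0.06). These counts were the same adjusted over the list alone. Too few members passed the expression filter for a test of fibroblast markers (2 of 14, none changed by edgeR), endothelial markers (4 of 12, 1 fell) and embryonal markers typical of HEK293 cells (3 of 12, 3 rose).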

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

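The GC and length correction, the restriction to genes with a GC value, the test against a fold change of 1.2 and the removal of VASP or of genes with the 3' UTR word were chosen after the data were examined. No paired analysis was possible because the columns of the control libraries carry no sample number that ties them to a numbered control sample. VASP kept its direction and its side of the threshold under every alternative, with a log2 fold change of -3.73 to -3.65 when each library was left out in turn and -3.54 after the GC and length correction. The number of changed genes was 4481 to 6399 when each library was left out, 5037 with DESeq2, and 6055 to 6196 under the other scalings, filters and limma-voom, and 6156 among genes with a GC value. Against a fold change of 1.2 it was 953, since small changes then do not pass. The number of genes changed at least 2-fold was 216 to 297 when each library was left out, 363 without a low-count filter, where more weakly expressed genes were tested, 101 with a filter of 1 CPM in 3 libraries, where fewer were, and 119 with DESeq2, where the cause was not tested. The number of lists called was 12 to 18 when each library was left out and 0 with an estimated correlation, and the cause was not tested. Of the 17 called lists, 9 kept the call under every alternative at the preset correlation, 4 lost it after the GC and length correction, which brought in 2 others, and 6 lost it in a fit without some library. Without a low-count filter, ATF4 targets (adjusted p = 0.021), ribosomal proteins (0.022) and Notch genes (0.049) also passed, while epithelial markers did not (0.073). With the filter of 1 CPM, epithelial markers (0.065) and fatty acid synthesis (0.055) did not pass. No camera call was lost or gained when VASP or the genes with the 3' UTR word were left out. By fry, leaving out VASP took the 18 lists with a call to 15. Among the lists that lost the call, only Ena/VASP partners held VASP. The others crossed the threshold narrowly: the fry adjusted p went from 0.048 to 0.051 for fatty acid synthesis and from 0.049 to 0.052 for leukocyte markers. Of 163 named genes with a call, 140 kept it under every alternative, 16 lost it after the GC and length correction, 10 when some library was left out and 3 with DESeq2 or without a low-count filter, and none of the 163 changed sign in any of these fits. The balance of the calls moved with the method, from 3148 genes up and 3039 down to 2702 and 3402 with upper-quartile scaling, 3417 and 2685 without a low-count filter, and 2822 and 2215 with DESeq2; the cause was not tested.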

Other observations

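The tests of GC response, of the other RNU6 copies and of the vector promoter were chosen only after the result was seen, as were the genes named in this part. Long noncoding RNAs fell more often than they rose. Of 711 tested with a mean log2 CPM of 1 or more, 46 rose and 169 fell by edgeR, in calls not corrected for GC content. Over all 16633 genes tested, at any level, 3148 rose and 3039 fell. Where such an RNA overlaps a gene on the other strand, unspliced RNA of that gene may be counted with it. UCA1, a long noncoding RNA first described in bladder cancer, rose 2.59-fold from 49.3 ± 2.02 to 128 ± 13.3 CPM (n = 3 each, adjusted p = 4.6e-12), with exons that overlap LINC01764, and LINC01293 rose 2.07-fold from 1.62 ± 0.306 CPM. Among the decreases, LINC01963 fell 2.23-fold from 15.1 ± 0.749 CPM (adjusted p = 4.8e-10) and ZEB1-AS1 fell 2.08-fold from 9.65 ± 0.282 CPM, whereas ZEB1, which it overlaps, rose 1.38-fold. Counts ignore strand, so each of the latter pair may hold reads from unspliced RNA of its partner, and both kept their direction after the GC and length correction, ZEB1-AS1 with a log2 fold change of -1.01 and ZEB1 with 0.35.

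Fold change fell with GC content, and each knockdown library had a lower GC slope than each control library. Slopes of the deviation from each gene's mean over the 6 libraries, which sum to 0 by construction, were 0.049 to 0.119 log2 units per 10 percentage points in control and -0.061 to -0.106 in knockdown. Loss of transcripts with the word GTCGTC is argued against, since among genes without the word anywhere in the transcript the Spearman correlation was -0.583, against -0.575 over all genes with a coding transcript. A bias of library preparation or sequencing predicts the trend in any class of transcript, and in 1128 noncoding genes the slope was -0.088 (95% interval -0.112 to -0.064), which excludes 0 but is shallower than the -0.160 of 11135 protein-coding genes. A response of the cells that follows GC content cannot be told apart from such a bias, because GC slope and group coincide: the difference of -0.154 has an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give.

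Genes with the word GTCGTCT in the 3' UTR fell more often than others, and among 15789 words of 7 bases scored in 10977 genes this word had the most extreme score (z -10.5, permutation p = 0.001, the smallest that 1000 permutations can give). The median adjusted log2 fold change was -0.13 in its 241 genes against 0.02 in the others. By calls not corrected for GC content, 49.4% of its genes fell against 21.1%. Base composition alone is argued against by the 98 words of the same bases with a CpG but without the core GTCGTC, whose lowest z was -3.17 and median z -0.254. Words with the core were left out, a choice not fixed beforehand, because they mark the same sites, and of these TGTCGTC, of the same bases, reached -9.01. A candidate explanation is that the knockdown reagent acts on other transcripts through a short match. It predicts that a word found in some genes also marks lower fold changes in others. The word chosen in every other gene by name was again GTCGTCT, and in the remaining genes its 119 genes lay lower. The mean difference was -0.172 log2 units (95% interval -0.227 to -0.116, permutation p = 0.0001, the smallest that 10000 permutations can give). Both sets of genes were measured in the same libraries, so the association holds across genes. Any cause tied to the word would give the same result, so it cannot single out the reagent. VASP has the core once, within AGTCGTCT in coding exon 11 of 13 (chromosome 19, 45524576 to 45524581 for the core, plus strand), although 11.9% of scanned words occur in its transcript and the reagent's sequence is not given in the sources used here.

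RNU6-1, a copy of the U6 small nuclear RNA gene, had 79, 87 and 68 counts in the control libraries and 1, 2 and 0 in the knockdown libraries. The ratio of summed counts, scaled by library totals, was 0.0127 (exact 95% interval 0.0026 to 0.0375, counting error only). The other 376 RNU6 copies with counts summed to 1535 counts in control and 1495 in knockdown, a ratio of 0.963 after scaling by library totals (95% interval 0.897 to 1.04). Fragments that align to several copies were not counted, so this sum cannot show whether carry-over of U6 RNA was lower in the knockdown libraries. Reads from a U6 promoter in a control vector, as the titles would allow, stay open as a possible explanation, because counts per gene do not show where reads start or end. The titles point to a hairpin vector in control and a hairpin against VASP in knockdown. They therefore do not by themselves predict such reads in the control libraries only.

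With 6 libraries there are 10 ways to form groups of 3, too few for a share under 0.05. The real grouping gave 6187 changed genes and the highest of the others 0, and 219 genes changed at least 2-fold against 0. For gene lists by camera at the preset correlation the real grouping gave 17 and the highest of the others 20, with 3 of the 10 reaching 17. The number of lists called by camera thus does not set the real grouping apart from groupings that mix the conditions. By fry, counted after the result was seen, the real grouping gave 18 lists, VASP included, and the highest of the others 0. Each of the other groupings mixes control and knockdown libraries, so the difference between conditions widens the spread within its groups. The counts of 0 therefore cannot show how many calls would arise without a difference between conditions.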
